A study of Rattus norvegicus with 4 samples.

How the data were processed

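Male Sprague-Dawley rats of 250 to 300 g received 75 mg/kg ANIT in olive oil (7.5 mg/mL) or the oil alone by intraperitoneal injection, per the labels, and 3 rats per treatment were killed at 12 h. RNA of the right lateral liver lobe was mixed within a treatment, poly(A) RNA was purified, and cDNA labelled with Cy3 or Cy5 was hybridised to spotted cDNA arrays said to hold 1800 rat genes, with GAPDH, HPRT and beta-actin as positive and Lambda DNA as negative control spots. There were 4 arrays, 2 of each dye orientation, in 1 group. The deposited values are 1 log ratio per spot and array. Scanner, background correction, normalization, filters, base of the logarithm and direction of the ratio are not given in the sources used here. The medians of all spots as deposited were -0.82, 0.37, -0.77 and 0.37 on arrays 1 to 4. Spot brightness was not part of the values, so signal over background is unknown.

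All arrays were read as holding the same treatment over the other, with no change of sign. The reason taken was the component that flips with the dye. Different probes of 1 gene differed in it with an SD 7.03 times its measurement SD. However, probes disagreed in both components nearly as widely as gene spots at large. That test therefore cannot tell which component holds the treatment, and the reading is an assumption. This reading was chosen after the values were seen, and no source states it. If each array instead held the same dye over the other, the dye contrast would be the treatment comparison.

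The spots form 16 blocks of equal size. At 18 positions per block no spot had an annotation in any block, and these 288 spots were taken as control spots from their layout, after a first look at the values, and left out. They fell into 5 sets, whose identity is not stated by the sources used here. Of the 1648 gene spots, 1432 had 1 gene symbol, 19 had several genes and 197 had no annotation in the table used. Symbols come from the platform annotation, and 1429 of the 1432 spots matched the rat gene table by Entrez identifier, with 0 symbols updated. Spots of 1 symbol were averaged (340 genes had over 1 probe) and spots with several genes or none were kept as unnamed. The medians of the arrays spanned 1.19, above the limit of 0.2 set beforehand, so each array was centred on the median of its gene spots.

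Differences were tested in limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0) on the log ratios, two-sided, with Benjamini-Hochberg adjustment over 1174 features and a threshold of 0.05. The samples, the main fit, the alternatives, the 27 gene lists and the rule for named genes were fixed before the data were examined. That fit tested the mean of the 4 arrays against 0 with 3 residual degrees of freedom. The fit with a dye effect for each gene had 2. The plan had assumed log2 values, and the values were used in their own unstated base. Lists were tested with camera at a preset correlation of 0.01 for the 19 lists with at least 5 measured genes. List members were also adjusted over their list alone in the fit with the dye effect, with no correction across lists. That adjustment was not in the plan and is more lenient. Unadjusted, 198 of 1174 features had a p under 0.05 in that fit. The rule named the 12 highest and 12 lowest genes past the threshold with the same direction on all 4 arrays, up to 4 called members per list or else its largest member, and the housekeeping genes. It was applied to the fit with the dye effect, with direction judged after each gene's dye effect was removed. All 32 named genes past the threshold met the direction condition in that form, so it excluded none. For the fit without the dye effect, the rule gave 10 genes per side as values only. These came out of 26 with the same direction on all 4 arrays, led by Cyp1a2, Ptma and Gpx2 and by Sytl1, Mt1 and Hipk3. Other genes named were picked after their values were seen. Both fits were tested on simulated data with known changes. Figures were drawn with matplotlib 3.10.9.

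Alternatives listed beforehand were values as deposited, equal spread on each array, the dye effect, filters on missing values, every probe on its own, robust eBayes, a size limit of 1 log unit, each array left out in turn, an estimated correlation and fry. After the data were examined, these were also run on the fit with the dye effect, with block centring, removal of a brightness trend, a variance trend, dim spots left out, control spots kept and fry on values as deposited as additions. The 4 arrays allow no split into groups of 3 or more, so other splits were not counted.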

Results

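Liver RNA of rats given alpha-naphthylisothiocyanate (ANIT), a toxicant that injures bile duct epithelium and causes cholestasis, was compared with liver RNA of rats given its vehicle, olive oil, at 12 h after injection. RNA of 3 rats per treatment was mixed, and both RNAs were hybridised together on 4 cDNA arrays. ANIT RNA carried Cy5 on arrays 1 and 3 and Cy3 on arrays 2 and 4. Each array held 16 blocks of spots with 0 missing values, and 1648 of the spots were gene spots. These gave 958 named genes and 216 unnamed spots, 1174 features in all. The values were log ratios whose base and direction were not stated by the sources used here, so sizes are given in log units and sides as positive or negative. The labels list ANIT as the second channel of every array. A positive value would therefore mean more transcript after ANIT if that channel was the numerator, and less if it was the denominator. No label says that the arrays held different RNA pools, so p-values measure the spread between hybridisations and compare the RNA pools, not animals. The number of arrays, 4, limits the precision.

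The question of the comparison was which liver transcripts differed between ANIT and olive oil. The named genes with the largest differences were Sytl1, which encodes a synaptotagmin-like protein of vesicle traffic, at -0.76 ± 0.051 log units (SE, n = 4 arrays), Mt1, the metal-binding protein metallothionein 1, at -0.70 ± 0.041, and Cyp1a2, a drug-oxidising cytochrome P450 of hepatocytes, at 0.62 ± 0.040. Cyp1a2 thus changed in the opposite direction to Sytl1 and Mt1, relative to the median gene spot of each array. In limma with a dye effect for each gene, the adjusted p was 4.42e-05 for each of these genes, and all 4 arrays lay on the same side for each. Sytl1 and Mt1 were measured by 1 spot each, as were Hipk3, Dtymk, Ptma and Gpx2 below, and Cyp1a2 by 2. The SE leaves out differences between probes. Over genes with several probes, the mean ratio differed within a gene with an SD of 0.080. As a fold, the difference in Cyp1a2 would be 1.54 if the logarithm has base 2, 1.86 if it is natural and 4.16 if it has base 10, and that in Mt1 would be 1.62, 2.01 and 4.97.

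**Figure D1:**
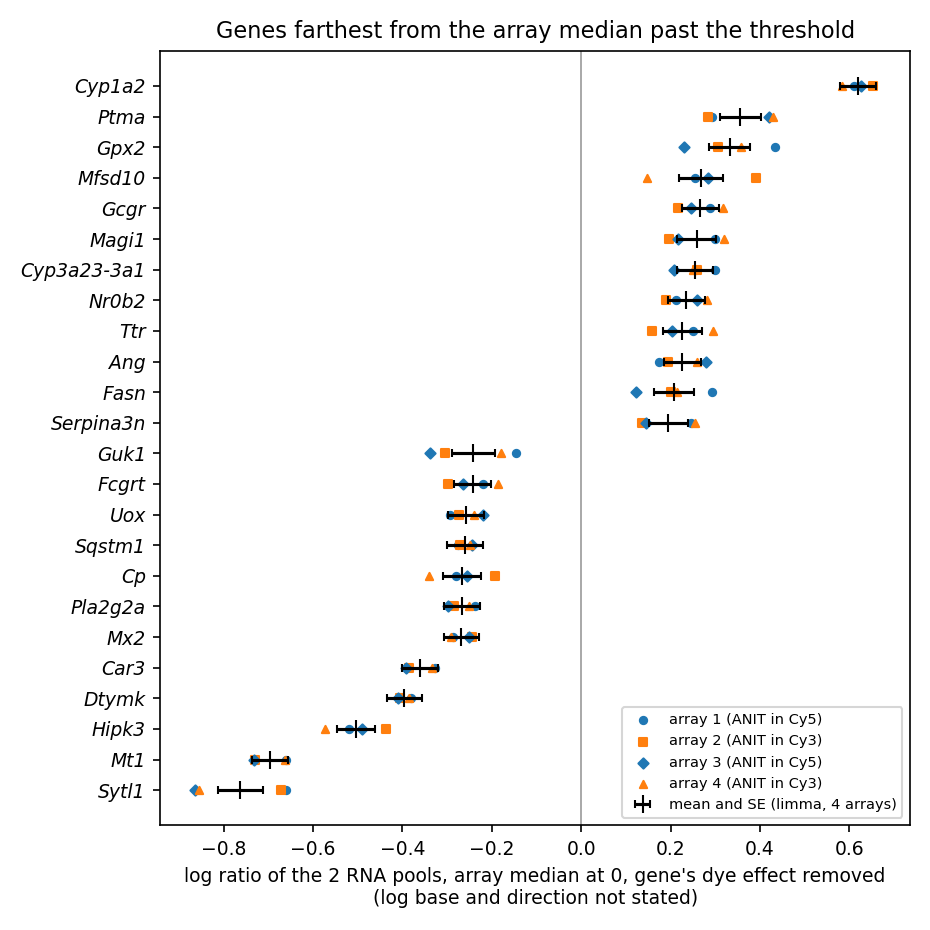
Log ratio of the 2 RNA pools (x axis, log units, base and direction not stated, array median at 0, each gene's dye effect removed) for the 12 named genes farthest on each side among those with adjusted p under 0.05. Points are the 4 arrays, and black bars are the limma mean and SE. Cyp1a2 at 0.62 lies apart on the positive side, and Sytl1 at -0.76 and Mt1 at -0.70 on the negative side.

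On the negative side, Hipk3, a protein kinase, followed at -0.50 ± 0.043 and Dtymk, the thymidylate kinase of nucleotide synthesis, at -0.40 ± 0.039. Car3, a cytosolic carbonic anhydrase abundant in rat liver, changed by -0.36 ± 0.040. Mx2, an interferon-induced GTPase, Pla2g2a, a secreted phospholipase, and Cp, the copper-carrying plasma protein ceruloplasmin, each stood at -0.27. Sqstm1, a receptor of selective autophagy, and Uox, the urate oxidase of hepatocyte peroxisomes, each stood at -0.26. Fcgrt, the receptor that recycles IgG and albumin, and Guk1, a guanylate kinase, each stood at -0.24. The adjusted p of these genes, from Hipk3 to Guk1, lay between 0.000194 and 0.0265. Before the dye effect was removed, all 4 arrays lay on the same side for Hipk3 and Guk1 alone among them. For the others the dye orientations had opposite signs, as in Car3 at 0.30, -1.01, 0.23 and -0.96 on arrays 1 to 4.

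On the positive side, Ptma, the nuclear protein prothymosin alpha, changed by 0.36 ± 0.046 and Gpx2, a glutathione peroxidase, by 0.33 ± 0.047. Mfsd10, a membrane transporter, and Gcgr, the glucagon receptor, each stood at 0.27, and Magi1, a scaffold of cell junctions, at 0.26. Cyp3a23-3a1, a cytochrome P450 of the drug-metabolising 3A family, stood at 0.25, and Nr0b2, the nuclear receptor SHP that represses bile acid synthesis genes, at 0.24. Ttr, the plasma carrier transthyretin, and Ang, the secreted ribonuclease angiogenin, each stood at 0.23, Fasn, the fatty acid synthase, at 0.21, and Serpina3n, a serine protease inhibitor of the acute phase, at 0.20. The adjusted p of these genes, from Ptma to Serpina3n, lay between 0.0033 and 0.0425. Before the dye effect was removed, all 4 arrays lay on the same side for Ptma, Gpx2 and Magi1 alone among them. For the others the dye orientations had opposite signs.

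Altogether 46 of 1174 features passed an adjusted p of 0.05 in limma with the dye effect, 19 on the positive and 27 on the negative side, and 32 of them were named genes (14 positive, 18 negative). The fit fixed before the data were examined had no dye effect in it, and there 0 of 1174 features passed, with 5 at an unadjusted p under 0.05. The fit with the dye effect was listed beforehand as an alternative and was chosen as the leading one after the data were examined. In simulated arrays with 1174 features, the fit without the dye effect called 0% of changes of 0.2 log units and 0% of changes of 0.6. The fit with it called 70% and 98%, with 0.72% of unchanged features called. The simulation was built from the dye effects and residual SDs that the fit with the dye effect gave here, with independent noise. That fit was thus right by construction, so the simulation shows only what each fit does when such dye effects are present. The position of 0 decides part of these directions. As deposited, the same fit passed 1061 features, 4 positive and 1057 negative. With 1 array left out it passed between 28 features, without array 3, and 86, without array 2. With values as deposited, in which the median of the gene spots' mean ratios was -0.22 log units, Cyp1a2 was at 0.40 and Ptma at 0.14, both still past the threshold, while Fasn stood at -0.0076 and Serpina3n at -0.020. A positive centred mean smaller than that shift is negative there, so sides are given relative to the median gene spot throughout. Ang, Mfsd10, Gcgr, Magi1, Cyp3a23-3a1, Nr0b2 and Ttr stayed positive there and no longer passed. In each of 14 alternative settings, 12 named genes passed the threshold on the same side. These were Cyp1a2 and Ptma on the positive side and Sytl1, Mt1, Hipk3, Dtymk, Car3, Mx2, Pla2g2a, Cp, Sqstm1 and Uox on the negative side. Among the settings were the filters on missing values, which could change nothing. Left out were the fit without the dye effect and the limit of 1 log unit, with 0 passing in each, and every probe on its own, where 1 of the 2 Cp probes passed. Values as deposited favour the negative side, so the larger number there is partly built in. Without array 3, Ang, Mfsd10, Nr0b2, Ttr, Serpina3n, Fcgrt and Guk1 no longer passed, and without array 1 Fasn, Ttr and Serpina3n did not. Serpina3n also missed it without array 4. With each print block centred on its own median, Gpx2 (0.25, adjusted p = 0.0623), Guk1, Fasn, Ttr and Serpina3n did not pass.

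Among groups fixed beforehand, the genes of iron and metal handling held calls on both sides of the median gene spot. Of 7 measured members, Mt1 and Cp changed on the negative side and Tf, the iron carrier transferrin, on the positive side at 0.19 ± 0.040 (adjusted p = 0.0368). The same 3 passed when adjusted over the list alone. Tf turned to -0.028 with values as deposited, and it did not pass without array 1, 3 or 4. In the acute phase list, 1 of 11 members changed on each side, Cp and Serpina3n. As a group the list did not stand apart in limma's camera test with the dye effect (adjusted p = 0.527). When adjusted over the list alone, 9 members passed, although their adjusted p over all features reached 0.25 in limma. Relative to the median gene spot, 6 of these were positive and 3 negative, and as deposited all 9 were negative. On the positive side with Serpina3n were Orm1 at 0.17, the complement protein C3 at 0.17, A2m at 0.15, Fgg at 0.13 and Serpina3c at 0.11, and on the negative side with Cp were the lipopolysaccharide-binding protein Lbp at -0.16 and Serping1 at -0.100. In the list of other proteins secreted by hepatocytes, 2 of 13 members changed, Ttr and Tf, and 4 passed when adjusted over the list alone, with Apob at 0.14 and Igf1 at -0.15 added. As deposited, Ttr was the 1 positive member of these 4.

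Among 18 measured targets of the oxidative stress regulator NRF2 and genes of glutathione metabolism, Gpx2 passed over all features. Its call was lost with print blocks centred. Adjusted over the list alone, 5 passed, all positive relative to the median gene spot, and as deposited 1 of them, Gpx2, was positive and 4 were negative. Beside Gpx2 these were the aldehyde dehydrogenase Aldh1a1 at 0.20, the quinone reductase Nqo1 at 0.20, the superoxide dismutase Sod1 at 0.17 and the glutathione transferase Gstm5 at 0.13. Of 24 cytochrome P450 and other phase I genes, 2 changed, Cyp1a2 and Cyp3a23-3a1, and the same number passed when adjusted over the list alone. Of 9 measured genes of bile acid synthesis and transport, Nr0b2 alone passed, both over all features and over the list. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at -0.065 ± 0.039, Cyp8b1 at -0.11 ± 0.043 and the canalicular export pump Abcc2 at -0.059 ± 0.041, none of them past the threshold.

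In lipid metabolism, 1 of 8 genes of fatty acid and triglyceride synthesis passed, Fasn, and 5 passed when adjusted over the list alone. Scd at 0.18, the lipoprotein lipase Lpl at 0.14 and the hepatic lipase Lipc at 0.11 lay on the side of Fasn, and Scd2 at -0.11 on the other. As deposited all 5 were negative. Lpl and Lipc break triglycerides down. Of 8 genes of fatty acid oxidation, Acsl1, an acyl-CoA synthetase, changed at -0.19 ± 0.041 (adjusted p = 0.0354), both over all features and over the list alone, but not without array 1, 3 or 4 or with print blocks centred. None of 4 cholesterol synthesis genes passed, with Acat2 at 0.086 the largest. None of 18 glucose metabolism genes passed, over all features or over the list. The largest of them, Khk, the ketohexokinase of fructose breakdown, stood at 0.16 ± 0.16, with array 2 at 0.80 and array 4 at -0.46. Without array 4 it was at 0.48 and without array 2 at -0.16. The remaining array of that orientation then has no spread of its own and is assumed to vary like the others. A p-value from such a fit says little about Khk. None of 4 amino acid catabolism genes passed, with Agxt at -0.058 the largest, and none of 3 oxidative phosphorylation genes, with Atp5pb at 0.059.

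Among stress and protein handling genes, Xbp1, a transcription factor of the unfolded protein response, was the 1 call among 10 heat shock and chaperone genes, at -0.20 ± 0.045 (adjusted p = 0.0425). It did not pass without array 1, 2 or 3, with equal spread on each array, with print blocks centred or with a brightness trend removed. Sqstm1 was the 1 call among 6 proteasome and ubiquitin genes. It is an autophagy receptor and no part of the proteasome, and the other 5 members were positive without passing, between 0.050 and 0.11, and so negative as deposited. Rpl6 was the 1 call among 13 genes taken for the ribosomal list, at -0.18 ± 0.039 (adjusted p = 0.0389). It did not pass without array 1, 2 or 3 or with equal spread on each array, and with print blocks centred it was at -0.12 (adjusted p = 0.198). That list was drawn by a name pattern that also took the kinase genes Rps6kb1, Rps6kb2 and Rps6ka4 and the pseudogene Rpl17-ps16. These 3 calls also passed over their lists alone. Of 16 cytokine and inflammation genes and 11 immediate early and damage genes, 0 passed over all features. Adjusted over each list alone, Stat3 passed at -0.17 ± 0.039 and Myc at -0.21 ± 0.052. Over all features and with all 4 arrays kept, Myc passed with equal spread on each array and Stat3 with robust eBayes and with control spots kept. Both passed with a variance trend and as deposited. Myc depended on single arrays, at -0.27 without array 2 and -0.14 without array 4. No gene passed, on either adjustment, among 12 cell cycle genes (Ccnd1 largest at 0.13), 14 coagulation and matrix turnover genes (Vtn largest at -0.13) and 10 cytoskeleton genes (Actr2 largest at 0.10).

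Markers of other liver cell types did not pass over all features or over their lists. The largest values were -0.12 for Fcgr2b among 5 myeloid and lymphoid markers, -0.095 for Timp1 among 13 endothelial, stellate and fibroblast markers, and -0.065 for Cd24 among 4 bile duct markers. Pf4 was the 1 erythroid and blood marker measured, at 0.0098. The dye component had a median of -0.72 for bile duct and -0.41 for myeloid and lymphoid markers. For endothelial, stellate and fibroblast markers it was -0.21. The bile duct median lay near those of sets B (-0.78) and E (-0.92) of the control spots. Signal over background is unknown, so a change in such markers may not have been measurable. Of the housekeeping genes that the labels name, Hprt1 stood at -0.011 ± 0.039 and Actb at 0.061 ± 0.051, neither past the threshold, and a value for Gapdh was not analysed here. With values as deposited, Pf4, Acat2, Atp5pb and Actb turned negative, as did Khk, Ccnd1 and Actr2 of the other groups. Timp1 (-0.31), Cd24 (-0.28), Hprt1 (-0.23), Pf4 (-0.21) and Actb (-0.15) passed there, among the 1061 features that did. Of the conjugating enzyme and clock gene lists, 0 members were measured.

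**Figure D2:**
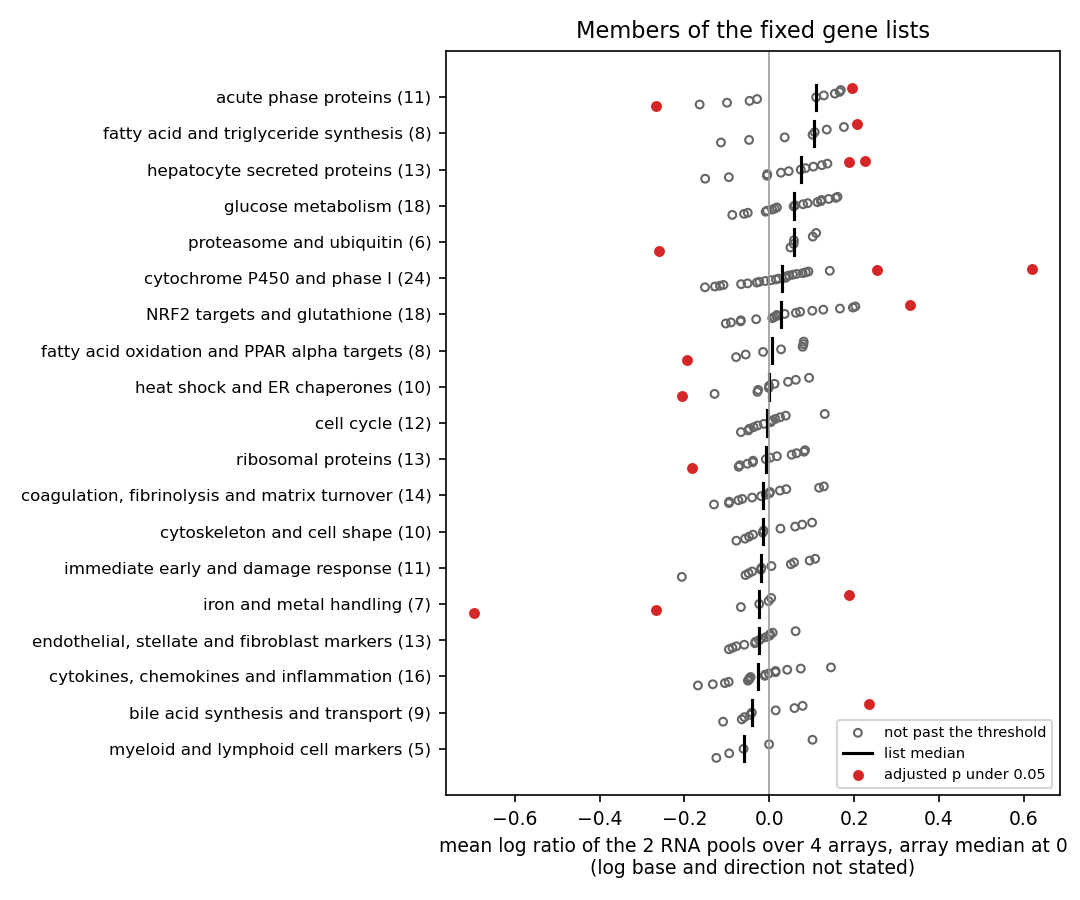
Mean log ratio of the 2 RNA pools over 4 arrays (x axis, log units, base and direction not stated, array median at 0) for the measured members of each fixed list with at least 5 measured genes, with the number measured in parentheses. Filled points passed an adjusted p of 0.05 over all 1174 features, and black bars are list medians. Mt1 at -0.70 and Cyp1a2 at 0.62 lie farthest out. With values as deposited the median gene spot lies at -0.22.

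As groups, 0 of the 19 lists with at least 5 measured genes stood apart from the other genes in limma's camera test with the dye effect. The smallest adjusted p was 0.17, for NRF2 targets, fatty acid and triglyceride synthesis, glucose metabolism and hepatocyte secreted proteins alike, with list medians of 0.027, 0.10, 0.059 and 0.074. At an unadjusted p under 0.05 those 4 lists passed, and 0 lists passed after adjustment with an estimated correlation. Limma's fry test, which asks whether a list's genes move on balance one way, passed 1 list, hepatocyte secreted proteins (adjusted p = 0.0159), on the positive side. On values as deposited it passed all 19 lists, on the negative side. Its mixed form, which asks for changes in either direction, passed 15. In the iron and metal list the median was -0.024 and the mean -0.12, with Mt1 as the outlying member. In the bile acid list the median was -0.041 and the mean 0.0079, of opposite sign, with Nr0b2 at 0.24 farthest out. Median and mean also differed in sign for fatty acid oxidation, cytoskeleton, bile duct and oxidative phosphorylation genes. For immediate early genes, camera and fry did. Without the dye effect the smallest adjusted p of camera was 0.051, for NRF2 targets, and 0 lists passed. There, leaving out array 2 or array 4 gave 7 lists each, all on the positive side, and leaving out array 1 or array 3 gave 0. In each case the arrays were then unequal in dye orientation.

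Under the reading of the arrays used here, the dye contrast, measured as the background of the ANIT comparison, was wider than the difference between the treatments. In limma, 970 of 1174 features differed between the dyes (456 positive, 514 negative), and the largest difference was 1.14 log units. Over gene spots the SD of the dye component was 0.48 and that of the mean ratio of the RNA pools 0.10, with a measurement SD of 0.084 for 1 array. Across the 1648 gene spots, which are not independent replicates, arrays of the same dye orientation correlated at r = 0.95 for arrays 1 and 3 and 0.95 for arrays 2 and 4. Arrays of opposite orientation correlated at r between -0.91 and -0.88. The mean of arrays 1 and 2 correlated with that of arrays 3 and 4 at r = 0.55 (rho 0.43), and the other dye-balanced pairing gave r = 0.52 (rho 0.39). The dye components of the hepatocyte secreted proteins had a median of 0.40 and those of the bile duct markers a median of -0.72, the 98.9 and 0.29 percentiles of random lists of equal size.

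**Figure D3:**
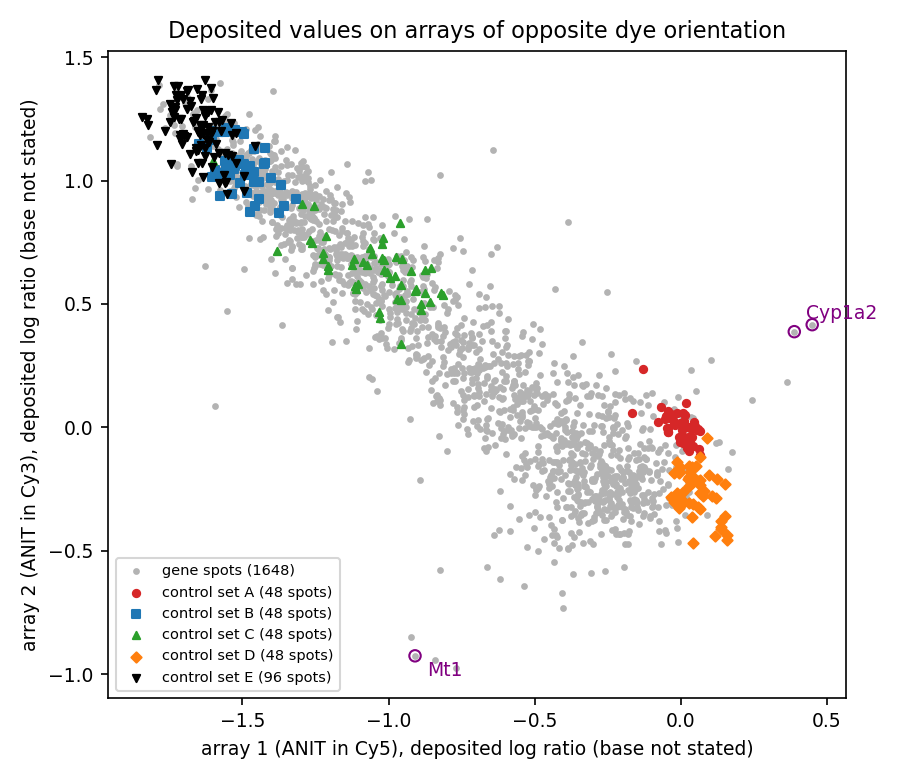
Deposited log ratio (base not stated) of each spot on array 1, with ANIT in Cy5 (x axis), against array 2, with ANIT in Cy3 (y axis). Grey points are the 1648 gene spots, coloured points are 5 sets of unnamed spots at recurring positions, and circles mark the spots of Cyp1a2 and Mt1. The arrays run against each other (r = -0.91 over gene spots). Cyp1a2 and Mt1 lie on opposite sides of the falling trend of the gene spots.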

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

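The test of the trend with spot brightness in this part was chosen after the result was seen.

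Ube2e2, a ubiquitin-conjugating enzyme, had array 2 far from the other arrays, with a gap of 0.93 of the whole range, above the critical value of Dixon's test for 4 samples. Its values were 0.23, 0.029, 0.23 and 0.22 log units on arrays 1 to 4, and its 2 probes stood at -0.10 and 0.46. Of 58 values tested in this way 1 stood out. The values still held the dye effect, which sets the arrays in pairs, so the test's usual rate of 1 in 20 by chance does not apply here and the count says little. With the dye effect removed, Ube2e2 stood at 0.18, 0.082, 0.18 and 0.27. Its mean of 0.18 did not pass in limma with the dye effect (adjusted p = 0.0753). The mean was 0.22 without array 2 and -0.038 as deposited.

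Among the control spots, which were left out of the comparisons except in 1 alternative setting, set A had a median mean ratio of 0.22 log units (SD 0.021 over 48 spots) and set D one of 0.11 (SD 0.039) relative to the median gene spot, both positive in 16 of 16 blocks. Sets B, C and E stood at 0.022, 0.023 and -0.023. As deposited, set A had medians within 0.011 of 0 on every array, and its largest block mean was 0.048 from 0. The median distance of its block means from 0 was 0.001, against 0.17 for set D and 0.87 to 1.48 for sets B, C and E. Brightness was not part of the values, so the dye component stood in for it without a check. On that reading, a trend of the ratio with spot brightness was argued against. Set A lay 0.23 above the 347 gene spots of the same dye component, of which 96.5% were below it. Scaling of each block to this set is a candidate explanation for its place at 0 that stays open, as the sources used here do not describe the scaling. No biological explanation was tested, and whether set A or the median gene is the better 0 stays open.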

How the results depend on the processing

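The added settings of the fit with the dye effect were chosen after the data were examined. Without the dye effect the count of genes stayed at 0 in every setting run, and adding it gave 46. With the dye effect (46, with 19 positive and 27 negative), the count of features was 1061 as deposited (4 positive, 1057 negative), 87 with every probe on its own, 93 with a variance trend, 102 with control spots kept (73 positive, 29 negative; 49 were control spots, all positive) and 0 at a size of at least 1 log unit. It ranged from 28 without array 3 to 86 without array 2, where the remaining array of that orientation is assumed to vary like the others. Equal spread on each array gave 56 (29 positive, 27 negative), robust eBayes 51, block centring 33, trend removal 47 and dim spots left out 47. Of the 32 named genes, 17 to 29 still passed with 1 array left out, 20 with blocks centred and 21 as deposited, where 28 kept their direction. The dye contrast was 772 as deposited (0 positive, 772 negative) and 931 to 959 with 1 array left out. The number of lists ranged from 0 to 7 without the dye effect and from 0 to 1 with it, with 1 array left out (iron and metal handling, without array 4, adjusted p = 0.0216), and fry gave 1, or 19 as deposited, all negative. As deposited, Pf4 turned to -0.21, Dgat1 to -0.11, Tf to -0.028, Acat2 to -0.13, Atp5pb to -0.16, Actb to -0.15, Fasn to -0.0076 and Serpina3n to -0.020, because the 0 moved by -0.22. For the other moves the cause was not tested. Filters on missing values moved nothing, as 0 values were missing. Each log ratio already set both RNAs of an array against each other, and no further pairing was used. Signal over background is unknown, and 5.28% of gene spots had a dye component at or below -0.78, near the upper end of control set E (median -0.92).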

Other observations

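The test of values stored as the same dye over the other and the deciding test of measurement noise were chosen after the results were seen.

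Genes whose response to liver injury is well known lay on both sides of 0, so they did not settle which side is ANIT. If positive means ANIT over oil, then Cyp1a2 (0.62), the glutathione peroxidase Gpx2 (0.33) and the quinone reductase Nqo1 (0.20) were higher after ANIT, and Mt1 (-0.70), Cp (-0.27) and Sqstm1 (-0.26) were lower. If it means oil over ANIT, all 6 turn. Gpx2, Nqo1, Mt1, Cp and Sqstm1 are all known as genes induced by oxidative or inflammatory stress. Nqo1 did not pass over all features (adjusted p = 0.0697), and its side also turned with the position of 0, to -0.018 as deposited. The direction was not tested, since no value in the files fixes it.

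Of the 46 calls, 14 were unnamed spots. An unnamed spot at -0.66 ± 0.044 lay directly before the spot of Mt1, at -0.70. Other unnamed spots stood at -0.65 and -0.52 on that side and at 0.51 on the positive side. The 9 called genes with 2 probes, Cp, Ang, Acsl1, Mx2, Cyp1a2, Car3, Pla2g2a, Serpina3n and Nr0b2, had both probes on the same side, as genes called on the mean of their probes often will. In Cp, Acsl1, Serpina3n and Nr0b2, 1 of the 2 probes passed when each was tested on its own. The probes of Cp stood at -0.16 and -0.37.

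Arrays of opposite dye orientation ran against each other over gene spots. Different probes of 1 gene differed in the dye component with an SD 7.03 times its measurement SD, against 1.45 times for the mean ratio. Over 3 times was taken to argue against a treatment effect stored as the same dye over the other. Within genes the SD was 0.39 against 0.48 over gene spots for the dye component, and 0.080 against 0.10 for the mean ratio. Probes of a gene thus disagreed in both nearly as widely as gene spots at large. The test therefore cannot tell which component holds the treatment. A dye effect that follows spot brightness may account for the opposite runs of the arrays. The hepatocyte secreted proteins, whose transcripts are abundant in liver, lay at the 98.91 percentile of random lists, and control set E lay at the 1.4 percentile of gene spots. The proteasome and ubiquitin list lay as high, at 99.24, so a high percentile was not particular to secreted liver proteins.

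Calls lay among the spots with a high dye component, read here as bright spots. That reading was not checked, as brightness was not part of the values. Probes of 1 gene differed in the component with an SD of 0.39. Brightest and dimmest below stand for the highest and lowest dye components. The brightest 391 features held 38 of the 46 calls, the 391 in the middle 6 and the dimmest 392 held 2. Larger measurement noise among dim spots as the whole cause was argued against, since the SD of the mean ratio among the dimmest features was 0.50 times that among the brightest. The test set beforehand had not decided, as the measurement SD was 1.48 times as high among the dimmest features. Background that pulls dim spots to the median cannot be told apart from a larger response of abundant liver transcripts such as Cyp1a2, and neither was settled by a test: the brighter probe had the larger ratio in 3 of 9 called genes, but the probes of a gene differed by at most 0.11 in the dye component (SD 0.48 over gene spots), too little contrast between dim and bright to bear on it.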
